A study of Mus musculus with 15 samples.

How the data were processed

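Total RNA from whole thymus was measured on 15 Affymetrix arrays of the type Mouse Gene 1.0 ST, 1 per mouse. The sample labels give 4 groups: NOD.Ln82-LCMV with the Db-binding control peptide (n = 4) or gp33 (n = 5), and NOD.LCMV with the control peptide (n = 3) or gp33 (n = 3). The deposited table holds log2 values of 35556 probe sets, which the authors made with RMA in Affymetrix Expression Console 1.1. No further normalization was applied. Array medians lay between 7.59 and 7.67, arrays of a group correlated across probe sets at 0.990 or more, and no pair of the 105 pairs of arrays shared more than 5.91% identical values. The number of arrays limits the precision.

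The annotation given with the platform named 23410 of the probe sets. A gene was represented by the probe sets with exactly 1 symbol (21789), and where several probe sets remained, as for 999 genes, by the one with the highest mean over all arrays, which left 19938 genes. The 12146 probe sets without annotation and the 1621 with several symbols were left out of the comparisons and only counted. Chromosomes and gene spans came from a gene table of the mouse assembly GRCm38.p6. The build behind the array annotation is not stated, so no coordinates are reported, and planned windows of fixed length along chromosome 7 became windows of 50 consecutive measured genes. The window from Zfp566 to Mag, which holds Nfkbid, had 22 of 50 genes called. It shared rank 2 of 35 windows with the window from Pagr1a to Prss8.

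All arrays entered 1 linear model in limma 3.58.1 (R 4.3.3) with a mean per group and empirical Bayes variances (11 residual and 14.9 total degrees of freedom). The comparisons were the response to gp33 in each strain, the difference between those responses, and the strain difference with the control peptide, with gp33 and averaged over both. Strain differences are NOD.LCMV minus NOD.Ln82-LCMV, and the difference between responses is that of NOD.LCMV minus that of NOD.Ln82-LCMV. Tests were two-sided and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes, with no limit on the fold. Some named genes were dim in at least 1 group (group mean under the dim limit given below), among them Il1b, Ifng, Gzmb, Ccl4, Mmp8, Pth and Kcnma1. No background level was measured, so how far it compressed their differences is not known. Intervals of folds are 95% intervals from the moderated standard error. Single values per mouse were compared by exact two-sided permutation tests of the difference of means, and for the difference between responses by exchanging the strain labels within each peptide. That exchange also breaks up the strain difference with gp33, so its p does not isolate the difference between responses.

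The comparisons, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. The 22 lists covered NF-κB genes, immediate early genes, T-cell activation, T-cell cytokines, feedback inhibitors of receptor signalling, apoptosis regulators, double-positive and mature single-positive thymocytes, cell cycle genes, glucocorticoid targets, heat shock genes, interferon-stimulated genes, thymic epithelium, B cells, dendritic cells and macrophages, granulocytes, fibroblasts, endothelium, adipocytes, red cells, skeletal muscle, and natural killer and γδ T cells. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists within a comparison, and their members were counted over all genes and adjusted over the list alone. Named genes were Nfkbid, up to 12 higher and 12 lower called genes with the largest difference in each comparison, up to 4 members of each list with the smallest adjusted p, and, for strain differences, up to 10 called genes of chromosome 7. Predicted and clone-named genes, small RNA genes, olfactory and vomeronasal receptors and antigen receptor segments were left out of the largest differences. Genes named outside this rule are marked where they appear.

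Shares of called genes per chromosome were compared by Fisher's exact test. The alternatives were a second quantile normalization, median centring, leaving out the dimmest 33.3% of the genes (mean log2 under 6.92), the mean over a gene's probe sets, every probe set on its own, a variance trend, array weights, only the groups compared, a limit of 1.5-fold, a replicate block for the NOD.Ln82-LCMV mice that share a number, and leaving out each array in turn. A trend on gene span, taken out of each array by lowess before the fit, was added after seeing the data. The model was tested on simulated data with 100 changed genes per fold in the real design and independent noise of equal spread on every array. It recovered 84 of 100 genes changed 1.25-fold in NOD.Ln82-LCMV and 62 of 100 in NOD.LCMV, with 13 and 17 false calls. The real arrays were less even, with array weights from 0.282 to 2.758, and far fewer genes were called in NOD.Ln82-LCMV. These shares therefore do not give the power in the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.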

Results

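Gene expression was measured in the whole thymus of 5-week-old female mice of the strains NOD.LCMV and NOD.Ln82-LCMV. The thymus was taken 2 h after 0.5 µg of peptide had been given into a vein. The peptide was gp33, a fragment of the lymphocytic choriomeningitis virus glycoprotein that Db class I molecules present to CD8 T cells, or a control peptide that also binds Db. Of the 15 arrays, 4 came from NOD.Ln82-LCMV mice given the control peptide and 5 from NOD.Ln82-LCMV mice given gp33. NOD.LCMV mice gave 3 arrays with each peptide, and the number of arrays limits the precision. The title of the series names Nfkbid as a gene of Idd7, a diabetes susceptibility locus, and asks about the deletion of CD8 T cells in the NOD thymus. The labels describe neither the Ln82 segment nor any processing batch, so a batch that followed the strain cannot be told apart from the strain. Values are log2, each difference is given with its standard error, and median log2 per array lay between 7.59 and 7.67 over all probe sets.

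Nfkbid encodes IκBNS, a nuclear protein of the IκB family that modulates NF-κB target genes, and lies on chromosome 7 (probe set 10551891). In NOD.LCMV it rose after gp33 by 2.13 ± 0.11 log2, a 4.39-fold rise with a 95% interval of 3.71 to 5.18 (limma adjusted p = 4.05e-09). Group means were 9.33 ± 0.07 (SD, n = 3) with the control peptide and 11.47 ± 0.06 (SD, n = 3) with gp33. In NOD.Ln82-LCMV the means were 9.19 ± 0.14 (SD, n = 4) and 9.61 ± 0.22 (SD, n = 5). That difference of 0.43 ± 0.09 log2 did not pass the test over all genes (limma adjusted p = 0.303), although each of the 5 gp33 mice lay above each of the 4 control mice (exact permutation p = 0.0159, 126 splits, two-sided). The responses of the strains differed by 1.71 ± 0.15 log2 (limma adjusted p = 2.16e-06; exact permutation p = 0.0173 over 1960 rearrangements). Without gp33, Nfkbid differed between the strains by 0.15 ± 0.10 log2, which did not pass the test (limma adjusted p = 0.477; exact permutation p = 0.257). With gp33 it was 3.62-fold higher in NOD.LCMV, with an interval of 3.12 to 4.20, and the exact permutation p of 0.0179 was the smallest that the 8 arrays allow. In NOD.LCMV alone, 3 mice against 3 cannot give an exact permutation p under 0.1, which was the value found.

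**Figure D1:**
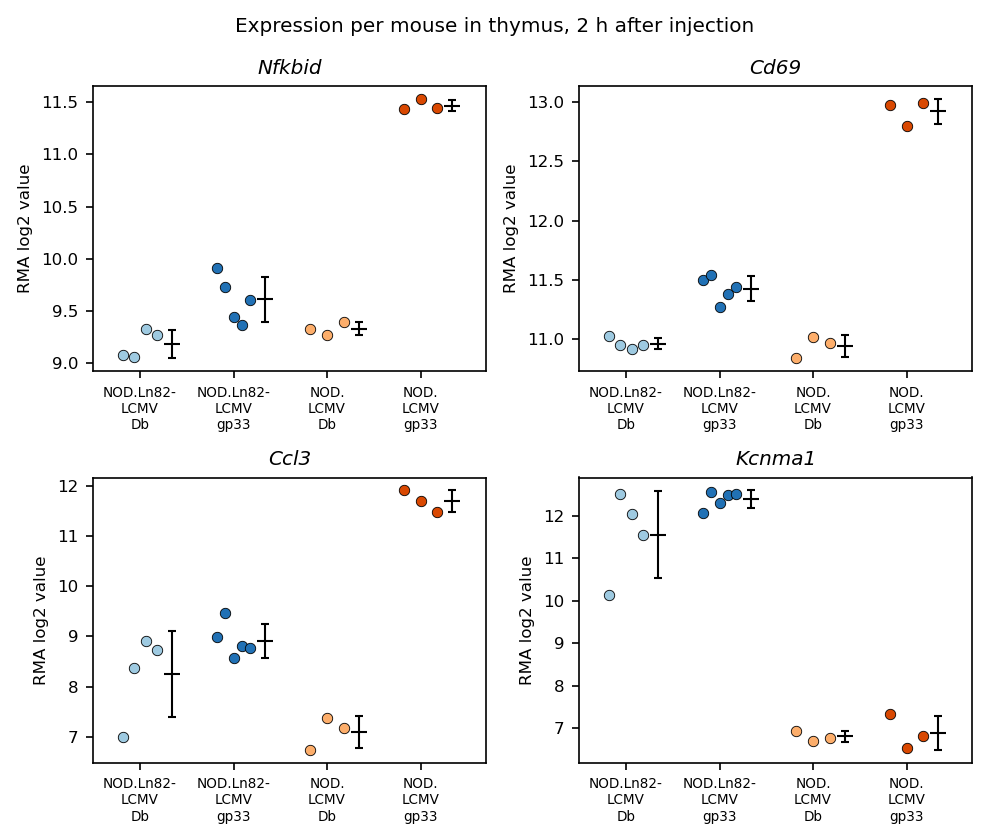
RMA log2 value (vertical axis) of Nfkbid, Cd69, Ccl3 and Kcnma1 in each mouse, by strain and peptide, with the group mean and SD beside the points. Nfkbid, Cd69 and Ccl3 are highest in the 3 NOD.LCMV mice given gp33, while Kcnma1 is lower in all 6 NOD.LCMV mice than in all 9 NOD.Ln82-LCMV mice.

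The response to gp33 in NOD.LCMV was a strong rise of chemokines, cytokines and transcription factors, some of which antigen receptor signals are known to induce. Whole thymus was measured, and which cells raised these genes was not tested. The largest rises were those of Ccl3, a chemokine of activated T cells and myeloid cells (4.60 ± 0.37 log2, 24.3-fold), and Xcl1, which attracts XCR1-bearing dendritic cells (4.47 ± 0.31 log2, 22.2-fold). Nr4a3, an orphan nuclear receptor induced by the T-cell receptor, rose by 4.02 ± 0.24 log2 (16.2-fold), and its relative Nr4a2 by 3.36 ± 0.16. The inflammatory cytokines Il1b (3.77 ± 0.16 log2) and Il1a (3.76 ± 0.16), the interferon-induced chemokines Cxcl10 (3.57 ± 0.22) and Cxcl9 (3.33 ± 0.19), and the matrix glycoprotein gene Thbs1 (3.25 ± 0.10) rose as well. So did Tagap, a GTPase-activating protein of activated T cells (3.64 ± 0.22 log2), Irf4, a transcription factor graded by receptor signal strength (3.61 ± 0.14), and Atf3, a stress-induced transcription factor (3.57 ± 0.09). In limma, 3943 of 19938 genes were called, 1453 higher and 2490 lower, and 195 of the rises but only 10 of the falls were at least 2-fold.

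Receptor-signal groups rose together in NOD.LCMV. In the list of NF-κB subunits, IκB proteins and NF-κB targets, which holds Nfkbid itself, 17 of 18 members rose over all genes, and 17 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.61e-35). They included Tnfaip3, a brake on NF-κB (1.74 ± 0.05 log2), Icam1, an adhesion molecule (1.69 ± 0.07), Relb, an NF-κB subunit (1.75 ± 0.08), and Birc3, an inhibitor of apoptosis (1.33 ± 0.06). Of 22 immediate early genes, 19 rose, and 20 adjusted over the list alone (camera adjusted p = 1.32e-32), among them Jun (1.92 ± 0.08 log2) and Myc (1.40 ± 0.07). Of 22 markers of T-cell activation, 19 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.74e-26). Cd69, a surface protein that appears within hours of receptor engagement, rose 3.94-fold (1.98 ± 0.07 log2), and Batf, a transcription factor of activated T cells, rose by 2.00 ± 0.12 log2. Of 14 cytokines of activated T cells, 10 rose, as they did adjusted over the list alone (camera adjusted p = 8.53e-16), with Ifng at 2.47 ± 0.14 log2, Tnf at 2.39 ± 0.15 and Ccl4 at 1.90 ± 0.12. Of 22 feedback inhibitors of receptor signalling, 16 rose over all genes, and adjusted over the list alone 17 rose and 2 fell (camera adjusted p = 1.45e-18). Spry1, an inhibitor of the MAP kinase pathway, rose by 2.57 ± 0.09 log2, the suppressor Cish by 1.91 ± 0.09, and Rgs16, which shortens G-protein signals, by 2.06 ± 0.14.

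Regulators of apoptosis changed in both directions in NOD.LCMV. Of 21 members, 10 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 5.26e-07). Bcl2l11, which encodes Bim, a killer protein of thymocytes under negative selection, rose by 1.73 ± 0.11 log2, Gadd45b by 3.22 ± 0.21, Gadd45g by 1.42 ± 0.08, and the death receptor gene Tnfrsf10b by 0.88 ± 0.05. Of 14 glucocorticoid targets, 8 rose, as they did adjusted over the list alone (camera adjusted p = 9.95e-08). These included Errfi1, a brake on EGF receptor signalling (1.59 ± 0.15 log2), the clock gene Per1 (1.01 ± 0.10), the metallothionein gene Mt2 (1.48 ± 0.16) and the MAP kinase phosphatase gene Dusp1 (0.82 ± 0.09). The other 6 were not called. Among them, Tsc22d3 stood at 8.62 to 8.78 with the control peptide and 8.60 to 8.88 with gp33, and Ddit4 at 9.55 to 9.70 and 9.17 to 9.71. Whether glucocorticoids caused the rises was not tested. Those 7 lists also passed camera with an estimated correlation, and the next 3 lists did not. Of 15 granulocyte markers, 7 rose, as they did adjusted over the list alone (camera adjusted p = 1.54e-06; adjusted p = 0.0604 with an estimated correlation), with the neutrophil collagenase gene Mmp8 at 1.43 ± 0.09 log2 and the G-CSF receptor gene Csf3r at 1.01 ± 0.07. Of 17 interferon-stimulated genes, 7 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 5.61e-08; adjusted p = 0.239 with an estimated correlation). Irf1, which interferon-γ induces, rose by 1.70 ± 0.05 log2 (0.59 on its second probe set) and the GTPase gene Gbp3 by 1.61 ± 0.10. Of 11 heat shock genes, 2 rose, as they did adjusted over the list alone (camera adjusted p = 0.00106; adjusted p = 0.267 with an estimated correlation). These were the chaperonin gene Hspd1 (0.33 ± 0.07 log2; 0.46 on its second probe set) and Hsph1 (0.46 ± 0.14), whose call was lost without NOD.LCMV control replicate 2 or 3 or gp33 replicate 2, with values between 0.30 and 0.56 log2 when 1 array was left out. Without NOD.LCMV gp33 replicate 1, 4 heat shock genes rose adjusted over the list alone.

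The genes that fell after gp33 in NOD.LCMV moved less than those that rose, and included surface proteins and coreceptors of T cells. The largest falls were those of Tdrp (−1.49 ± 0.29 log2), the carboxypeptidase gene Cpm (−1.47 ± 0.18) and Card6 (−1.37 ± 0.18). Cd7, a T-cell surface glycoprotein (−1.26 ± 0.22), and Itgae, which encodes the integrin CD103 (−1.15 ± 0.18), also fell. Klhl4 fell by 1.16 ± 0.31 log2, a call lost without NOD.LCMV gp33 replicate 2 (range with 1 array left out −1.28 to −1.03). Of 21 genes of double-positive thymocytes, 8 fell and 1 rose, and 10 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00645; adjusted p = 0.526 with an estimated correlation). The coreceptor gene Cd8a (−0.51 ± 0.09 log2), the lipid-presenting molecule gene Cd1d1 (−0.56 ± 0.12) and the signalling adaptor gene Themis (−0.40 ± 0.09) fell, and Cd24a rose (0.38 ± 0.07). Of 12 endothelial markers, 3 fell, and 6 adjusted over the list alone (camera adjusted p = 0.00371; adjusted p = 0.267 with an estimated correlation), with Pecam1 at −0.61 ± 0.06 log2 and Eng at −0.91 ± 0.12. Of 15 fibroblast genes, 2 fell, as they did adjusted over the list alone (camera adjusted p = 0.0153; adjusted p = 0.409 with an estimated correlation), namely Thy1, which thymocytes express as well (−0.44 ± 0.06 log2), and the growth factor receptor gene Pdgfrb (−0.49 ± 0.07). Camera calls of single lists rested on single arrays. The endothelial and fibroblast calls were lost without NOD.LCMV control replicate 1 (camera adjusted p = 0.0609 and 0.186), and the double-positive call without NOD.LCMV gp33 replicate 2 (camera adjusted p = 0.118). Control replicate 1 had the highest means of the 6 NOD.LCMV arrays for the endothelial and fibroblast lists and also for adipocyte genes (10.11 against 8.59 to 9.60). Over all genes, 5, 4 and 3 double-positive genes fell without NOD.LCMV control replicate 1, control replicate 2 and gp33 replicate 2. The 3 endothelial genes became 5 without NOD.LCMV control replicate 3 or NOD.Ln82-LCMV gp33 replicate 5. Adjusted over the list alone, 3 endothelial genes fell without NOD.LCMV control replicate 1 or 2 or gp33 replicate 3, and 7 fibroblast genes without NOD.LCMV control replicate 3.

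The other lists did not pass camera in NOD.LCMV, but several held genes that changed. Of 17 genes of mature single-positive thymocytes, 4 fell over all genes, and adjusted over the list alone 7 fell and 2 rose (camera adjusted p = 0.303). The 7 became 4 without NOD.LCMV control replicate 1 or 2, gp33 replicate 2 or 3, or NOD.Ln82-LCMV gp33 replicate 2. S1pr1, the receptor through which thymocytes leave the thymus, fell by 0.85 ± 0.07 log2, the integrin gene Itgb7 by 0.78 ± 0.09, and the chemokine receptor genes Ccr7 by 0.65 ± 0.15 and Ccr9 by 0.40 ± 0.07. Of 12 markers of natural killer and γδ T cells, 3 rose and 1 fell, and adjusted over the list alone 3 rose and 2 fell (camera adjusted p = 0.0649, and 0.0282 at the lowest, without NOD.LCMV control replicate 1 or gp33 replicate 2). The risers are also genes of activated CD8 T cells: Tbx21, which encodes T-bet (3.12 ± 0.13 log2), the granzyme gene Gzmb (2.06 ± 0.14) and Eomes (0.37 ± 0.08). Of 21 dendritic cell and macrophage markers, 2 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.494). Ccl22, a chemokine of mature dendritic cells, rose by 1.52 ± 0.11 log2, whereas Xcr1, the receptor for Xcl1 (−0.67 ± 0.08), Clec9a (−0.72 ± 0.10) and Mertk (−0.53 ± 0.11) fell. Of 18 thymic epithelial markers, 2 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.76), and the list's median of −0.09 log2 (−0.03 without NOD.LCMV gp33 replicate 2) lay opposite to camera's upward direction. Ccl19, a chemokine for maturing thymocytes, rose by 0.93 ± 0.16 log2, and the thymoproteasome gene Psmb11 fell by 0.53 ± 0.14. Of 13 B-cell genes, the coactivator gene Pou2af1 alone rose (0.91 ± 0.13 log2; camera adjusted p = 0.822, upward, against a list median of −0.20, or −0.34 to −0.06 with 1 array left out), and of 20 cell cycle genes Ccne1 alone fell (−0.24 ± 0.06 log2; camera adjusted p = 0.681). Limma called 0 of 14 adipocyte genes (camera adjusted p = 0.494), 0 of 7 red cell genes (camera adjusted p = 0.681) and 0 of 11 muscle genes (camera adjusted p = 0.76), and 0 in each list also at an unadjusted p under 0.05. The adipocyte list was called without NOD.LCMV control replicate 3 (camera adjusted p = 0.00586).

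In NOD.Ln82-LCMV the response to gp33 was small. Cd69 rose by 0.46 ± 0.06 log2 (1.38-fold, 95% interval 1.26 to 1.5, limma adjusted p = 0.0215) and was the 1 gene called. Of 19938 genes, 1190 had an unadjusted p under 0.05, and 641 without control replicate 1. Chance alone gives a share of about 0.05, so these counts do not show a broad response. Other genes of receptor signalling had higher means without passing the test: Tagap by 1.14 ± 0.18 log2 (limma adjusted p = 0.0717), Xcl1 by 1.11 ± 0.25 (0.374), Nr4a1 by 0.86 ± 0.17 (0.219), Nr4a3 by 0.89 ± 0.20 (0.357) and Irf4 by 0.56 ± 0.12 (0.219). The Cd69 call was lost without control replicate 2, 3 or 4 or gp33 replicate 1, 3, 4 or 5 of this strain, while its log2 difference stayed between 0.44 and 0.50. A second gene was called without control replicate 1 (Tagap, 0.91 log2), without gp33 replicate 2 (Il1a, 0.93 log2) and without NOD.LCMV gp33 replicate 2 (Gem, 0.53 log2, chosen for naming after its value was seen).

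Lists of receptor signalling moved upward in NOD.Ln82-LCMV at camera's preset correlation. The T-cell activation list held the 1 called gene among 22, and 7 members rose adjusted over the list alone (camera adjusted p = 1.59e-11), the only list of 22 to pass with an estimated correlation (adjusted p = 0.0141). The 7 became 4 without control replicate 1 or gp33 replicate 1. Of 18 NF-κB genes, limma called 0 over all genes and 11 adjusted over the list alone, with 12 higher at an unadjusted p under 0.05 (camera adjusted p = 1.47e-17; adjusted p = 0.0532 with an estimated correlation). Relb and Rel, both NF-κB subunits, had differences of 0.35 ± 0.07 log2 each and Birc3 of 0.24 ± 0.05. Of 22 immediate early genes, limma called 0 over all genes, and adjusted over the list alone 7 rose and 1 fell, as they did at an unadjusted p under 0.05 (camera adjusted p = 1.14e-09; adjusted p = 0.116 with an estimated correlation). Adjusted over the list alone, 4 rose without control replicate 2 or 4 and 3 without gp33 replicate 1 or 5. Of 17 interferon-stimulated genes, limma called 0 over all genes, 2 adjusted over the list alone and 4 at an unadjusted p under 0.05 (camera adjusted p = 2.22e-05; adjusted p = 0.352 with an estimated correlation). The median of this list, 0.14 log2, was 0.04 without control replicate 1, whose list mean was 8.91 against 9.28 to 9.44 on the other control arrays, and 0.23 without control replicate 4. Cytokines of T cells (0 of 14 over all genes, 1 adjusted over the list alone, 2 unadjusted) had a camera adjusted p of 0.000162, or an adjusted p = 0.21 with an estimated correlation. Feedback inhibitors (0 of 22 both ways, 6 unadjusted) had a camera adjusted p of 0.000691, or an adjusted p = 0.21 with an estimated correlation.

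Lists of other cell types also passed camera with its preset correlation in NOD.Ln82-LCMV, although no member was called. Thymic epithelium moved up (median 0.16 log2; 5 of 18 members at an unadjusted p under 0.05 in limma; camera adjusted p = 8.06e-08; adjusted p = 0.21 with an estimated correlation). Without gp33 replicate 5, 12 of them rose adjusted over the list alone. Granulocyte markers also moved up (median 0.13 log2; 4 of 15 unadjusted; camera adjusted p = 2.22e-06; adjusted p = 0.116 with an estimated correlation). B cells (median 0.18 log2; 1 of 13 unadjusted) had a camera adjusted p of 0.000341, or an adjusted p = 0.352 with an estimated correlation. Natural killer and γδ T cells (median 0.08 log2; 1 of 12 unadjusted and adjusted over the list alone) had a camera adjusted p of 0.00583, or an adjusted p = 0.202 with an estimated correlation. Dendritic cells and macrophages (median 0.10 log2; 1 higher and 1 lower of 21 unadjusted) had a camera adjusted p of 0.0248, and double-positive thymocytes, the one list that moved down (median −0.08 log2; 1 of 21 unadjusted), of 0.0112, each with an adjusted p = 0.608 with an estimated correlation. Without control replicate 1 the medians were 0.09 for thymic epithelium, 0.04 for B cells, 0.05 for natural killer and γδ T cells, 0.003 for dendritic cells and −0.04 for double-positive thymocytes. That array had the lowest mean of the epithelial list among the 4 control arrays (9.73 against 9.89 to 10.04). The B-cell median was 0.27 without control replicate 4, the dendritic median 0.05 without control replicate 2 and 0.06 without gp33 replicate 3, and the double-positive median −0.055 without gp33 replicate 5. The B-cell call was lost without control replicate 1 of this strain (camera adjusted p = 0.232), an array whose B-cell list mean was 7.67 against 8.24 to 8.45 on the other 3 control arrays. The dendritic call was lost without control replicate 1 or 2 or gp33 replicate 3 or 4 (camera adjusted p up to 0.431), and the double-positive call without control replicate 1 or gp33 replicate 1 or 5 (up to 0.448).

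An activation score, the mean log2 value of 80 genes from the immediate early, activation, cytokine and feedback lists, gives 1 value per mouse. In NOD.LCMV it was 8.79 ± 0.03 (SD, n = 3) with the control peptide and 10.03 ± 0.08 (SD, n = 3) with gp33, a difference of 1.24 log2 at the smallest exact permutation p that 6 arrays allow, 0.1. In NOD.Ln82-LCMV it was 8.86 ± 0.07 (SD, n = 4) and 9.04 ± 0.09 (SD, n = 5), a difference of 0.18 log2 with every gp33 mouse above every control mouse (exact permutation p = 0.0159). Without control replicate 1 that difference was 0.15 log2 and no longer passed (exact permutation p = 0.0536). The responses differed by 1.06 log2 between the strains (exact permutation p = 0.00102 over 1960 rearrangements, of which the smallest possible is 0.00051). The strains' scores did not pass the test with the control peptide (−0.08 log2, exact permutation p = 0.114). With gp33 they differed by 0.99 log2 (exact permutation p = 0.0179, the smallest possible).

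**Figure D2:**
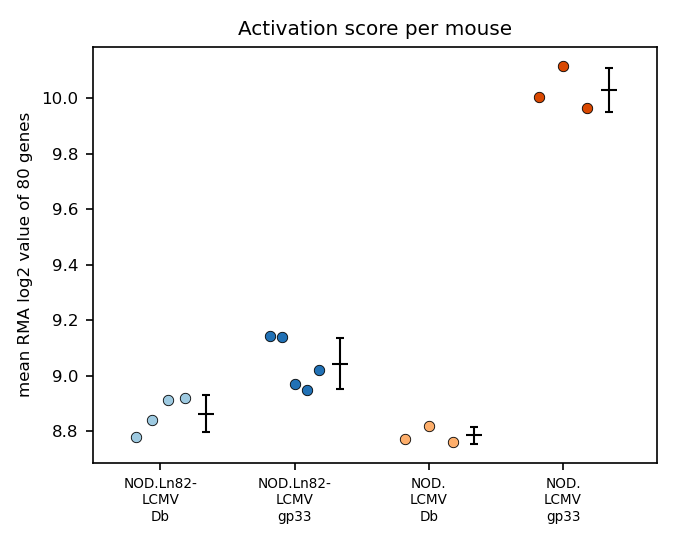
Activation score of each mouse (vertical axis, mean RMA log2 value of 80 genes) by strain and peptide, with the group mean and SD. The 3 NOD.LCMV mice given gp33 lie between 9.96 and 10.12, and the 5 NOD.Ln82-LCMV mice given gp33 between 8.95 and 9.14.

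The response to gp33 itself differed between the strains, tested as an interaction, and genes of receptor signalling were among the largest differences. Limma called 1740 genes, 890 with a higher and 850 with a lower value of the NOD.LCMV response minus the NOD.Ln82-LCMV response, and 163 of the higher were at least 2-fold. The difference was largest for Ccl3 (3.94 ± 0.48 log2, 15.3-fold), Xcl1 (3.36 ± 0.40), Il1b (3.34 ± 0.21) and Atf3 (3.33 ± 0.12). It was 3.24 ± 0.13 log2 for Thbs1 (9.47-fold), 3.05 ± 0.17 for Ccn1, a matrix protein gene induced by growth signals, 2.95 ± 0.18 for the interferon-induced GTPase gene Gbp5, and 2.95 ± 0.17 for Tbx21. Nr4a3 (3.13 ± 0.31 log2), Nr4a2 (2.90 ± 0.21), Irf4 (3.05 ± 0.18) and Il1a (2.90 ± 0.20) differed as well. Lower values in NOD.LCMV were smaller in size and included Card6 (−1.14 ± 0.23 log2), Cpm (−1.04 ± 0.23), the Notch-induced repressor gene Hey1 (−1.03 ± 0.16), the iron exporter gene Slc40a1 (−0.86 ± 0.17) and the natural killer receptor gene Klrd1 (−0.84 ± 0.16). Cd7 (−1.11 ± 0.28) lost its call without NOD.LCMV control replicate 1 or 2 or gp33 replicate 2 (−1.35 to −0.86). Itgae (−0.96 ± 0.24) lost its call without NOD.LCMV gp33 replicate 2 (−1.13 to −0.78).

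**Figure D3:**
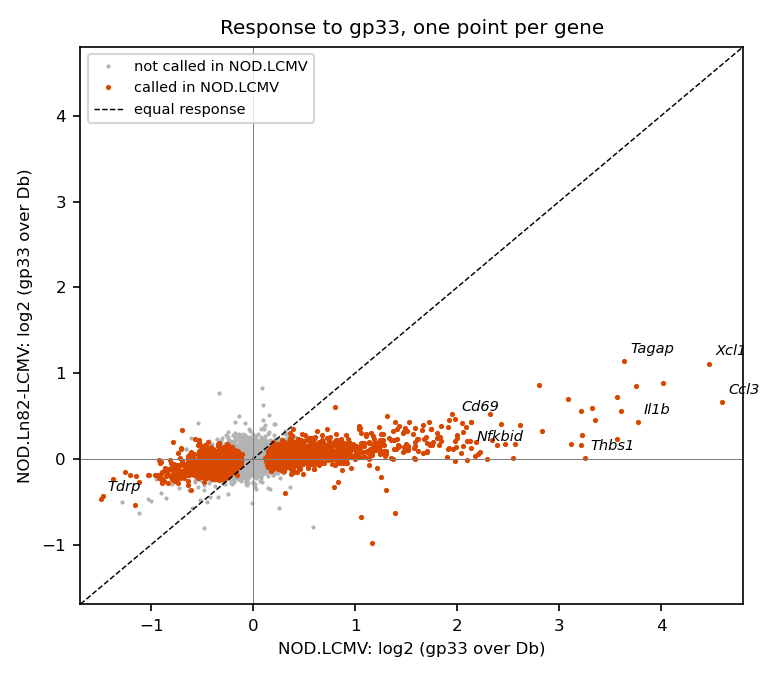
Response to gp33 of each of 19938 genes as log2 of gp33 over control peptide, in NOD.LCMV (horizontal axis) and NOD.Ln82-LCMV (vertical axis), with the 3943 genes called in NOD.LCMV in orange and the line of equal response dashed. Of the 205 genes called at 2-fold or more in NOD.LCMV, 194 have the same sign in NOD.Ln82-LCMV.

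By group, the difference between the responses was higher in NOD.LCMV for 17 of 18 NF-κB genes, over all genes and adjusted over the list alone (camera adjusted p = 1.22e-39), with Tnfaip3 at 1.57 ± 0.07 log2 and Relb at 1.39 ± 0.11. It was higher for 17 of 22 immediate early genes, 18 adjusted over the list alone (camera adjusted p = 2.06e-34), and for 9 of 14 cytokines both ways (camera adjusted p = 4.56e-15), with Ifng at 2.30 ± 0.19 log2 and Tnf at 2.22 ± 0.20. Of 22 activation markers it was higher for 15 and lower for 1, and 19 and 1 adjusted over the list alone (camera adjusted p = 1.29e-26), with Cd69 at 1.51 ± 0.09 log2 and the interferon regulatory factor gene Irf8 at 1.41 ± 0.12. Of 22 feedback inhibitors it was higher for 12, and adjusted over the list alone for 15 with 1 lower (camera adjusted p = 2.07e-19), with Spry1 at 2.40 ± 0.12 log2. For apoptosis regulators it was higher in 8 of 21, and adjusted over the list alone in 9 with 1 lower (camera adjusted p = 1.05e-07), with Bcl2l11 at 1.29 ± 0.14 log2 and Gadd45b at 2.66 ± 0.27. For glucocorticoid targets it was higher in 7 of 14, and 8 adjusted over the list alone (camera adjusted p = 3.53e-09). These 7 lists also passed with an estimated correlation.

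The response of 5 further lists differed in camera at the preset correlation only. Fry also called the interferon, granulocyte and endothelial lists (fry adjusted p = 0.0217 at most). It did not call the heat shock and fibroblast lists (fry adjusted p = 0.0624 and 0.0801). Interferon-stimulated genes were higher for 4 of 17, 5 adjusted over the list alone (camera adjusted p = 1.75e-06; adjusted p = 0.279 with an estimated correlation), with Irf1 at 1.63 ± 0.07 log2 (0.58 on its second probe set) and Cxcl9 at 2.73 ± 0.25. Granulocyte markers were higher for 7 of 15, and adjusted over the list alone for 7 with 1 lower (camera adjusted p = 0.000232; adjusted p = 0.171 with an estimated correlation). The granulocyte list's median was −0.004 log2 (−0.05 to 0.11 with 1 array left out) while its mean of 0.30 and camera pointed up. Heat shock genes were higher for 1 of 11, 3 adjusted over the list alone (camera adjusted p = 0.000232; adjusted p = 0.242 with an estimated correlation). The 3 became 1 or fewer without control replicate 1 or 2 or gp33 replicate 2 of NOD.Ln82-LCMV, or without control replicate 2 or 3 or gp33 replicate 2 of NOD.LCMV. Endothelial markers were lower for 3 of 12 both ways (camera adjusted p = 0.00619; adjusted p = 0.279 with an estimated correlation), with Eng at −0.70 ± 0.15 log2, and this call was lost without NOD.LCMV control replicate 1 (camera adjusted p = 0.109). Adjusted over the list alone they became 5 without NOD.LCMV control replicate 3. Fibroblast genes were lower for 2 of 15 both ways (camera adjusted p = 0.0423; adjusted p = 0.558 with an estimated correlation). The fibroblast call was lost without control replicate 1 or 4 or gp33 replicate 3 or 4 of NOD.Ln82-LCMV, or without NOD.LCMV control replicate 1 or gp33 replicate 2 (camera adjusted p up to 0.346). S1pr1 (−0.65 ± 0.09 log2) and Itgb7 (−0.60 ± 0.12) were lower although the list of mature thymocyte genes did not pass camera (2 of 17 lower, 3 adjusted over the list alone; camera adjusted p = 0.222). Without NOD.LCMV gp33 replicate 1 these counts were 4 and 7, and without NOD.Ln82-LCMV control replicate 1 the first was 4.

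**Figure D4:**
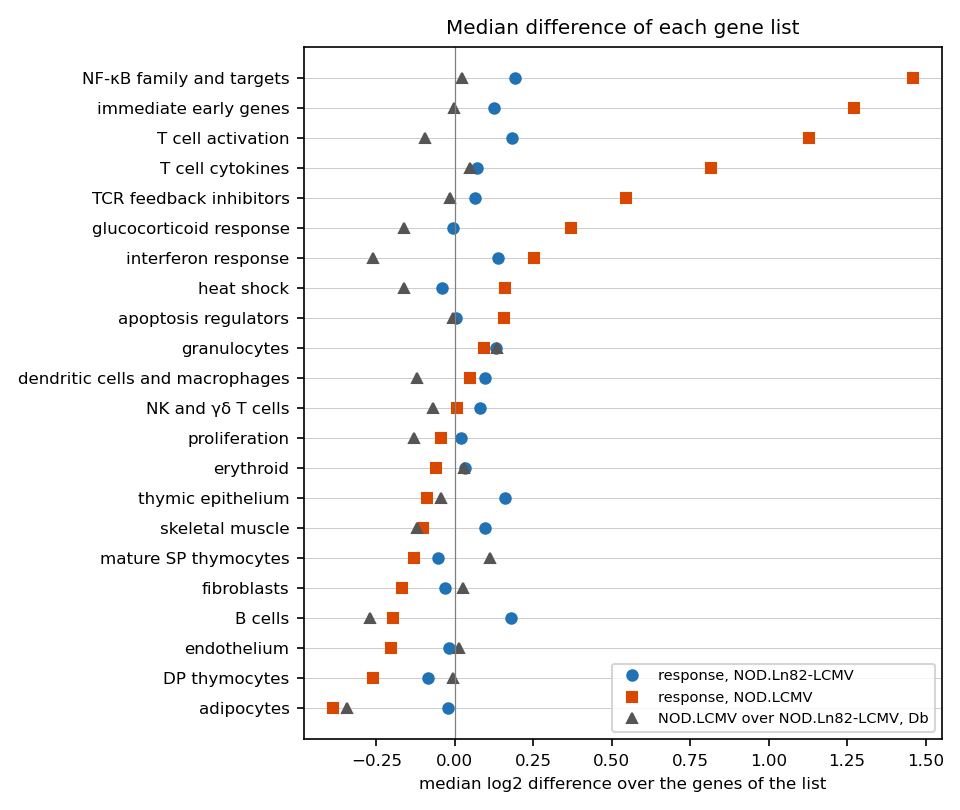
Median log2 difference over the measured genes of each of the 22 lists (horizontal axis) for the gp33 response in NOD.Ln82-LCMV (circles), the gp33 response in NOD.LCMV (squares) and NOD.LCMV minus NOD.Ln82-LCMV with the control peptide (triangles). The NF-κB list has a median of 1.46 in the NOD.LCMV response, 0.19 in the NOD.Ln82-LCMV response and 0.02 between the strains with the control peptide.

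With the control peptide the largest difference between the strains was that of 1 of the 2 probe sets of a potassium channel gene. The signal of Kcnma1, which encodes the pore of the BK potassium channel, was lower in NOD.LCMV (−4.76 ± 0.38 log2; limma adjusted p = 2.38e-05), with means of 6.80 ± 0.12 (SD, n = 3) against 11.56 ± 1.03 (SD, n = 4). The second probe set of Kcnma1 differed by −0.08 log2, so the difference is that of the first probe set. Whether it comes from expression or from a sequence difference under the probes was not tested. Lower in NOD.LCMV were also Uprt, related to uracil phosphoribosyltransferases (−1.47 ± 0.18 log2; −0.99 on its second probe set), Ly6d, a surface protein of B-lineage progenitors (−1.37 ± 0.26), Ly96, which encodes the partner of Toll-like receptor 4 (−1.34 ± 0.18), Pth, the parathyroid hormone gene (−1.13 ± 0.20), and Fcer1g, the common Fc receptor γ chain gene (−0.91 ± 0.14). The acyl-CoA thioesterase gene Acot2 (−0.99 ± 0.14 log2) and the cytochrome b5 reductase gene Cyb5r3 (−0.91 ± 0.12) were lower too. Higher in NOD.LCMV were Bach2, a transcriptional repressor of lymphocytes (0.87 ± 0.17 log2), Adam11 (0.87 ± 0.16), Tbrg3 (0.83 ± 0.09), Zfp831 (0.82 ± 0.18), Xkrx (0.80 ± 0.14) and Pced1b (0.74 ± 0.09). Limma called 2057 genes, 952 higher and 1105 lower in NOD.LCMV, of which 3 and 13 were at least 2-fold. The count fell to 1188 without NOD.Ln82-LCMV control replicate 3, to 1310 without NOD.LCMV control replicate 2 and to 1049 without NOD.LCMV control replicate 3, and was 2721 without NOD.Ln82-LCMV control replicate 1, with 1957 genes shared.

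Several of the largest differences with the control peptide lost their call when single arrays were left out, while they kept their direction. The adhesion receptor gene Cd226 was higher in NOD.LCMV (1.21 ± 0.29 log2), a call lost without NOD.Ln82-LCMV control replicate 3 or NOD.LCMV control replicate 3 (1.05 to 1.61 log2). Itgae was higher (0.71 ± 0.17 log2), a call lost without NOD.Ln82-LCMV control replicate 3 or NOD.LCMV control replicate 1 or 2 (0.63 to 0.89). Prxl2a was lower (−1.45 ± 0.36 log2), a call lost without control replicate 2 or 3 of either strain (−1.90 to −0.96). Ccl3 was lower (−1.16 ± 0.34 log2), a call lost without any 1 array except control replicate 1 and gp33 replicate 1 of NOD.Ln82-LCMV (−1.57 to −0.94). On NOD.Ln82-LCMV control replicate 1, Cd226 stood at 10.10, within the NOD.LCMV control range of 10.05 to 10.18 and above the 8.34 to 8.64 of the other 8 NOD.Ln82-LCMV arrays. Of 67 named genes called, 33 kept their call whichever array was left out.

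The lists that passed camera with the control peptide did so at the preset correlation only, and each of the 8 had an adjusted p = 0.495 with an estimated correlation. Cell cycle genes were lower in NOD.LCMV for 7 of 20 members, and 11 adjusted over the list alone (camera adjusted p = 6.21e-07). The 7 became 4 without NOD.Ln82-LCMV control replicate 3 or NOD.LCMV control replicate 2 or 3, and the 11 became 7 without the last. The cyclin genes Ccna2 (−0.31 ± 0.05 log2) and Ccnb2 (−0.20 ± 0.04), the spindle checkpoint gene Bub1 (−0.28 ± 0.05) and the thymidylate synthase gene Tyms (−0.38 ± 0.06) were among them. Heat shock genes were lower for 3 of 11, and 5 adjusted over the list alone (camera adjusted p = 0.000424), with Hspe1 at −0.39 ± 0.08 log2. The counts were 1 and 3 without NOD.Ln82-LCMV control replicate 3 and 1 both ways without NOD.LCMV control replicate 3, and the second was 3 without control replicate 2 of either strain. Interferon-stimulated genes were lower for 2 of 17, and 4 adjusted over the list alone (camera adjusted p = 0.000424). Without NOD.Ln82-LCMV control replicate 1 the counts were 7 and 11. They were 1 or fewer both ways without control replicate 2, 3 or 4 of that strain or control replicate 2 or 3 of NOD.LCMV, and the first was 4 without NOD.LCMV gp33 replicate 1 or 2. Their member Bst2 (−0.45 ± 0.11 log2) lost its call without NOD.LCMV control replicate 3 (−0.37 log2). Dendritic cell and macrophage markers were lower for 4 of 21, and 6 adjusted over the list alone (camera adjusted p = 0.00295). The complement genes C1qa (−0.50 ± 0.12 log2) and C1qc (−0.49 ± 0.12) were among them, and their calls were lost without NOD.LCMV control replicate 3 (−0.40 and −0.42 log2). Without that array the list held 1 or fewer called members both ways, and without NOD.Ln82-LCMV control replicate 3 it held 2 both ways. Over all genes it also held 2 without NOD.Ln82-LCMV control replicate 4.

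The other lists that passed depended on single arrays as well. B-cell genes were lower for 1 of 13 both ways, Cd79b (camera adjusted p = 0.00295), a list call lost without NOD.LCMV control replicate 3 (camera adjusted p = 0.0781). Without NOD.Ln82-LCMV control replicate 1, 4 were lower over all genes and 10 adjusted over the list alone, and the latter count was 6 without NOD.LCMV control replicate 1. The call of Cd79b over all genes was lost without NOD.Ln82-LCMV control replicate 2, 3 or 4 or NOD.LCMV control replicate 2 or 3. The B-cell list mean was 7.67 on NOD.Ln82-LCMV control replicate 1, against 8.24 to 8.45 on the other 3 control arrays of that strain. Glucocorticoid targets were lower for 3 of 14 both ways, including Mt2 at −0.73 ± 0.15 log2 (camera adjusted p = 0.0235, lost without NOD.Ln82-LCMV control replicate 2 or NOD.LCMV control replicate 3, up to 0.216). Over all genes 1 was lower without NOD.Ln82-LCMV control replicate 2 or 4 or NOD.LCMV control replicate 2 or 3, the last also adjusted over the list alone. Granulocyte markers were higher for 2 and lower for 1 of 15, and higher for 3 and lower for 1 adjusted over the list alone, with the lactoferrin gene Ltf at 0.42 ± 0.09 log2 (camera adjusted p = 0.0235, lost without NOD.Ln82-LCMV control replicate 2 or NOD.LCMV control replicate 1, up to 0.131). Adjusted over the list alone, 1 was higher without control replicate 2 or 3 of either strain and 6 without NOD.LCMV gp33 replicate 3. Genes of mature thymocytes were higher for 3 of 17 both ways, including the CD8-lineage factor Runx3 at 0.46 ± 0.10 log2 (camera adjusted p = 0.0324, lost without NOD.Ln82-LCMV control replicate 2 or 4 or NOD.LCMV control replicate 1, up to 0.156). Without NOD.Ln82-LCMV control replicate 1 the counts were 6 over all genes and 7 adjusted over the list alone. Over all genes 1 was higher without NOD.LCMV control replicate 3, and adjusted over the list alone 5 without NOD.LCMV gp33 replicate 2. Limma called 0 of 18 NF-κB genes with the control peptide, with 1 higher and 2 lower at an unadjusted p under 0.05 (camera adjusted p = 0.917). Among apoptosis regulators, the effector gene Bak1 (−0.38 ± 0.05 log2) and the caspase gene Casp8 (−0.31 ± 0.06) were lower in NOD.LCMV. Their list did not pass (1 higher and 3 lower of 21, 1 and 5 adjusted over the list alone; camera adjusted p = 0.192). The 3 became 5 without NOD.Ln82-LCMV gp33 replicate 5, and the 5 became 3 without control replicate 3 or 4 of that strain or control replicate 1 or 3 of NOD.LCMV.

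With gp33 the strains differed in genes of receptor signalling and in several genes that also differed with the control peptide. Ccn1 was 10.7-fold higher in NOD.LCMV (3.42 ± 0.12 log2) and Thbs1 10.6-fold (3.40 ± 0.09). Il1b (3.32 ± 0.15), Atf3 (3.28 ± 0.08) and Irf4 (2.90 ± 0.13) were among the other higher genes. The first probe set of Kcnma1 was lower (−5.50 ± 0.36 log2; −0.10 in the second, with the same reservation about its cause). Uprt (−1.81 ± 0.17; −1.3 on its second probe set), Ly6d (−1.80 ± 0.25), Ly96 (−1.77 ± 0.17), Acot2 (−1.41 ± 0.13) and the Wnt antagonist gene Sfrp1 (−1.36 ± 0.15) were lower as well. Limma called 5386 genes, 2032 higher and 3354 lower, of which 165 and 42 were at least 2-fold. Lists that passed with either correlation were those of NF-κB (17 of 18 higher; camera adjusted p = 1.9e-26), immediate early genes (19 of 22, and 20 adjusted over the list alone; 1.28e-23) and activation (19 higher and 1 lower of 22, and 20 and 1 adjusted over the list alone; 6.55e-18). Feedback inhibitors (15 higher and 1 lower of 22, and 17 and 1 adjusted over the list alone; 1.27e-13) and cytokines (10 of 14 higher, and 10 with 1 lower adjusted over the list alone; 3.16e-11) passed likewise. Apoptosis regulators passed both ways too, with 11 higher and 4 lower of 21, and 12 and 5 adjusted over the list alone (camera adjusted p = 0.000196).

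Markers of other cell types differed between the strains given gp33, mostly downward in NOD.LCMV. Their lists passed camera only at the preset correlation. Adipocyte genes apart (fry adjusted p = 0.14), the lists given here also passed fry (adjusted p = 0.024 at most). B-cell genes were lower for 7 and higher for 1 of 13, and 11 and 1 adjusted over the list alone (camera adjusted p = 0.00331; adjusted p = 0.492 with an estimated correlation). The 11 became 7 without NOD.Ln82-LCMV gp33 replicate 3 or 4 and 6 without NOD.LCMV gp33 replicate 2 or 3. The B-cell receptor chain genes stood at −1.48 ± 0.26 log2 (Cd79a) and −1.30 ± 0.18 (Cd79b). Thymic epithelial markers were lower for 9 and higher for 1 of 18 both ways (camera adjusted p = 0.0131; adjusted p = 0.622 with an estimated correlation), with Psmb11 at −0.75 ± 0.12 log2 and Foxn1, the master regulator of thymic epithelium, at −0.54 ± 0.09. Cell cycle genes were lower for 14 of 20, and 16 adjusted over the list alone (camera adjusted p = 9.78e-06; adjusted p = 0.133 with an estimated correlation), with Ccna2 at −0.42 ± 0.04 log2. Endothelial markers were lower for 6 of 12, and 7 adjusted over the list alone (camera adjusted p = 0.0131; adjusted p = 0.379 with an estimated correlation). Both counts were 3 without NOD.LCMV gp33 replicate 1, and the first also without gp33 replicate 3. Dendritic cell and macrophage markers were lower for 10 and higher for 1 of 21 both ways (camera adjusted p = 0.0323; adjusted p = 0.622 with an estimated correlation), with Xcr1 at −0.80 ± 0.07 log2 and Mertk at −0.77 ± 0.10. Over all genes 6 were lower without NOD.LCMV gp33 replicate 2. Granulocyte markers were higher for 7 and lower for 1 of 15 both ways (camera adjusted p = 9.78e-06; adjusted p = 0.0912 with an estimated correlation). Glucocorticoid targets were higher for 7 of 14, and for 7 with 1 lower adjusted over the list alone (camera adjusted p = 0.000693; adjusted p = 0.192 with an estimated correlation). Adipocyte genes were lower for 2 of 14, and 1 adjusted over the list alone (camera adjusted p = 0.0448; adjusted p = 0.677 with an estimated correlation). Without NOD.Ln82-LCMV gp33 replicate 1 the counts were 6 and 9. The dendritic call was lost without NOD.Ln82-LCMV gp33 replicate 3 or 4 or NOD.LCMV gp33 replicate 2 (camera adjusted p up to 0.167), and the adipocyte call without control replicate 1 or gp33 replicate 3, 4 or 5 of NOD.Ln82-LCMV or NOD.LCMV gp33 replicate 1 (up to 0.166).

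Averaged over both peptides, the strains differed at 5522 genes, 2409 higher and 3113 lower in NOD.LCMV. The first probe set of Kcnma1 was lower (−5.13 ± 0.26 log2; −0.09 in the second). Uprt (−1.64 ± 0.12; −1.15 on its second probe set), Ly6d (−1.59 ± 0.18), Ly96 (−1.55 ± 0.12) and Acot2 (−1.20 ± 0.10) were lower at both peptides. Bach2 (1.37 ± 0.11 log2) and the adhesion molecule gene Crtam (1.40 ± 0.09) were higher. Cell cycle genes were lower for 17 of 20 both ways (camera adjusted p = 9.68e-08; adjusted p = 0.0695 with an estimated correlation). B-cell genes were lower for 8 of 13, with 9 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000529; adjusted p = 0.435 with an estimated correlation). The NF-κB, immediate early and activation lists, which did not pass with the control peptide, passed in the average with either correlation (adjusted p = 0.035, 0.035 and 0.0315 with an estimated correlation).

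On chromosome 7, which carries Nfkbid, 406 of 1734 genes were called in the averaged strain difference, 23.4% against 28.2% on the other chromosomes (Fisher's exact test, adjusted p = 0.000392 over the chromosomes). It was not alone in this: the share was also lower on chromosome 6 (23.7%, adjusted p = 0.0136) and chromosome 2 (25.1%, adjusted p = 0.0415), and higher on chromosome 11 (31.4%, adjusted p = 0.012). With the dimmest 33.3% of the genes left out the shares were 37.7% and 41.5% and no longer differed past the threshold (Fisher's exact test, adjusted p = 0.246), and for calls with the control peptide alone they were 9.86% and 10.4% (adjusted p = 0.682). The share stayed lower at an adjusted p under 0.01 (15.9% and 19.1%; adjusted p = 0.0164) and for calls with gp33 alone (21.5% and 27.6%; adjusted p = 3.49e-07). Near Nfkbid the share was higher: 18 of its 40 nearest measured neighbours were called, 45% against 22.9% of the rest of the chromosome (Fisher's exact p = 0.00216). Among genes above the dim limit it was 50% against 35.6% (Fisher's exact p = 0.111). In the windows of 50 genes along the chromosome the share ranged from 0% to 46%. These Fisher's tests, and those of whole chromosomes, count genes, which are not independent. Their p-values do not measure spread between mice. Called neighbours included Haus5, a centrosome protein gene (−0.58 log2), Igflr1 (0.39), the RNA polymerase subunit gene Polr2i (−0.38), the signalling adaptor gene Tyrobp (−0.39) and the histone methyltransferase gene Kmt2b (0.35), chosen for naming after their values were seen. Elsewhere on the chromosome Emp3 (−0.81 ± 0.05 log2), Vps33b (−0.80 ± 0.06), Gdpgp1 (−0.74 ± 0.06) and Pth (−1.0 ± 0.14) were lower in NOD.LCMV, and were lower with the control peptide too (−0.73, −0.76, −0.52 and −1.13 log2). The peptide hormone gene Adm (1.02 ± 0.07 log2), the IκB family gene Bcl3 (0.79 ± 0.08), the urokinase receptor gene Plaur (0.77 ± 0.06) and Relb (0.74 ± 0.05) were higher in the average. With the control peptide they stood at 0.02, 0.05, 0.09 and 0.04 log2 and were not called.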

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

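The counts over other splits of the arrays were planned, whereas the removal of a trend on gene span and all other tests of explanations in this part were chosen after the results were seen. The tests of a wrong label and of fewer B cells on control replicate 1 of NOD.Ln82-LCMV were changed after their first values were known. A first count, of named genes at least 2-fold above each other control array of the strain, gave 4 for replicate 1, 4 for replicate 2 and 0 for replicates 3 and 4. Counted at least 2-fold below, it gave 5 for replicate 1, 10 for replicate 4 and 0 for replicates 2 and 3. Neither count set replicate 1 apart.

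The response to gp33 differed between the strains by limma's test of the difference itself, which called 1740 genes. The activation score differed by 1.06 log2 (exact permutation p = 0.00102, from the exchange of strain labels). The difference was 1.71 log2 for Nfkbid, 3.94 for Ccl3, 3.36 for Xcl1, 3.34 for Il1b, 3.33 for Atf3, 3.24 for Thbs1, 3.13 for Nr4a3, 3.05 for Irf4, 3.05 for Ccn1, 2.95 for Gbp5, 2.95 for Tbx21, 2.90 for Il1a and 2.90 for Nr4a2. On the other side it was −1.14 for Card6, −1.11 for Cd7, −1.04 for Cpm, −1.03 for Hey1, −0.96 for Itgae, −0.86 for Slc40a1 and −0.84 for Klrd1. With strain labels exchanged within each peptide, 3 of 100 drawn splits, the real one included, gave at least 1740 genes. This share cannot exclude chance for the difference between responses, because the exchange also breaks up the strain difference with gp33. The 4 other drawn splits that kept the real gp33 groups each gave at least 1185 genes. The highest other split gave 5645, several times the real count. That split and the one with 1856 both kept the real gp33 groups. The split with 5645 set NOD.Ln82-LCMV control replicates 2, 3 and 4 on the side of the NOD.LCMV gp33 mice. With the controls exchanged in this way, a strain difference that both peptides share adds up instead of cancelling. The averaged strain difference itself had 5522 called genes. Among splits that broke up the gp33 groups, the highest count was 1403.

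For the single gene of the NOD.Ln82-LCMV response, 3 of 100 splits gave at least 1 gene, the real one included. The other such splits gave 3 and 6 genes, more than the real one, so a count of 1 cannot exclude chance. Chance was excluded at 0.05 for the strain difference with gp33 (1 of 56 splits, real count 5386, highest other 2). For the averaged strain difference the real split gave the most genes as well (1 of 100 splits, 5522, highest other 3224). Most of those splits also broke up the strain difference with gp33. They therefore cannot exclude chance for a difference that both peptides share. The 6 arrays of the NOD.LCMV response make 10 splits, too few for a share under 0.05 (real count 3943, highest other 1).

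Single arrays lay far from the rest of their group in 21 of 304 tests on genes and list means (gap over range, Dixon), where chance gives about 1 in 20 groups. Of the 21, 16 were among the NOD.Ln82-LCMV controls and 14 came from control replicate 1. Replicate 1 was highest for Adam11 (0.933), Bach2 (0.872), Cd226 (0.864), Itgae (0.833), Klhl4 (0.855), Pced1b (0.867), Runx3 (0.860), Tdrp (0.871) and Themis (0.870). It was lowest for Emp3 (0.923), Tagap (0.928), Xcl1 (0.974), the T-cell receptor segment Trbv1 (0.955; chosen after its values were seen) and the mean of the T-cell activation list (0.869). Hspd1 was low on control replicate 4 (0.909) and the glucocorticoid list high on control replicate 2 (0.839). With gp33, replicate 5 was lowest for Cd24a (0.735) and Mertk (0.75) and highest for Gadd45g (0.759), and replicate 1 was highest for Gbp5 (0.774) and the cell cycle list (0.854).

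Control replicate 1 of NOD.Ln82-LCMV stood apart, with Tdrp at 10.34 log2 (8.55 to 8.99 in the other 8 mice of its strain; 10.21 to 10.26 in NOD.LCMV controls) and the B-cell gene Ms4a1, chosen after its values were seen, at 7.23 (8.20 to 9.55). A NOD.LCMV mouse under the wrong label is argued against, since 51.9% of 162 genes that separated the strains lay nearer to the NOD.Ln82-LCMV mean (93.2% to 98.1% on the other control arrays of that strain), against at most 21.1% for a NOD.LCMV control array left out in turn, and Uprt (10.58) lay within its own strain (10.39 to 10.65; NOD.LCMV 8.52 to 9.71). Fewer B cells in the tissue are argued against for the genes higher in NOD.LCMV, of which 34 of 42 lay nearer to NOD.LCMV on replicate 1, against 8, 1 and 1 on the other control arrays (Fisher's exact test, p = 1.75e-08 at most), while the lower B-cell genes remain open. Many of the 42 were microRNA genes, as were all of the 8, 1 and 1. This Fisher's test and the next count genes on single arrays, which are not independent, so their p-values do not measure spread between mice. RNA of both strains in 1 sample is argued against as the whole cause, since at the best single share 98 of the 162 genes lay outside the range of such mixtures, against 40 to 53 on the other control arrays (Fisher's exact test, p = 8.2e-07 at most), whereas a mouse of mixed genotype stays open and was not tested. The design puts this mouse in no group of its own, so apart from fewer B cells no biological explanation was tested.

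With the control peptide 2057 genes differed between the strains, and chance cannot be excluded, because 2 of 35 splits gave as many; the other (2082) set control replicate 1 of NOD.Ln82-LCMV with the 3 NOD.LCMV controls. Gene span alone is argued against: genes higher in NOD.LCMV were longer (median 44.4 kb against 11.1 kb for lower ones), yet after a trend on span was taken out 1785 genes were called. Of these, 1640 were among the 2060 called without it over the genes with a known span. Sequence differences on chromosome 7 alone are argued against by the 10.4% of genes called on the other chromosomes (9.86% on the whole of chromosome 7, which says nothing of any part of it), and control replicate 1 as the source by 2721 called genes without it (1049 and 1310 without NOD.LCMV control replicates 3 and 2, 1188 without NOD.Ln82-LCMV control replicate 3). Strain, as an untested biological difference, cannot be told apart from a batch, since the labels give none and a batch could follow strain.

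In NOD.Ln82-LCMV 1 gene was called with gp33, against 3943 in NOD.LCMV. A complete failure to deliver the peptide is argued against by the activation score, which rose (exact permutation p = 0.0159). Without control replicate 1 the exact permutation p was 0.0536. Partial delivery in this strain was not tested and stays open. Spread from control replicate 1 as the cause is argued against by the 2 genes called without it. For the mean of the 80 score genes, a raised baseline is argued against. The control groups differed by 7.27% of the difference between the responses. For single genes a raised baseline stays open. Of 22 activation markers, 6 were lower and 1 higher in NOD.LCMV with the control peptide, adjusted over the list alone. Ccl3 stood at 8.38 to 8.91 in NOD.Ln82-LCMV control replicates 2 to 4, at 7 in replicate 1 and at 6.74 to 7.37 in NOD.LCMV controls. What sets the strains apart in this response stays open, with the strain itself as an untested biological difference. A constant offset between the strains would cancel within each strain. Handling that followed strain and changed the response itself would not cancel, and cannot be told apart from strain. The sample titles take a different form in each strain, and the labels do not say whether handling differed. The T-cell receptor segment Trbv1 separated the strains, apart from control replicate 1 of NOD.Ln82-LCMV, where it stood at 10 log2. It stood at 8.5 to 10.31 log2 in NOD.LCMV and at 12.54 to 12.66 in the other 8 NOD.Ln82-LCMV mice. Whether the thymi of the strains differed in their T-cell receptors, and whether this bears on the response, was not tested.

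A signal also lay outside the measured genes. Of 13767 probe sets without a single gene name, which no comparison uses, 505 were called in the NOD.LCMV response to gp33 and 103 in the difference between responses (limma). In the NOD.Ln82-LCMV response limma called 0 (575 at an unadjusted p under 0.05, a smaller share than chance alone gives). Between the strains 1521 were called with the control peptide, 2325 with gp33 and 3792 on average.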

How the results depend on the processing

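The correction for gene span was chosen after seeing the data, and the other alternatives were planned. No score and, Als2cl apart, no named gene that was called reversed its direction under these alternatives. In the difference between responses, more genes were higher than lower (890 and 850), but fewer without NOD.Ln82-LCMV control replicate 1 (938 and 1016). Als2cl, higher in NOD.LCMV with the control peptide by 0.76 log2, stood at −0.08 on its second probe set. The lists called by camera kept the direction camera gave when any 1 array was left out, whereas lists that were not called changed it in every comparison (8 of 10 in the NOD.Ln82-LCMV response, 7 of 14 between the strains with the control peptide). Of 528 counts of called list members, 191 moved over 1.5 times without at least 1 array, 149 of them counts of 2 or fewer. Medians of called lists moved as far for 8 of 12 in the NOD.Ln82-LCMV response, 7 of 13 in the NOD.LCMV response, 3 of 12 in their difference, and 4 of 8, 2 of 14 and 2 of 13 between the strains with the control peptide, with gp33 and on average. Without 1 array, Nfkbid ranged from 2.10 to 2.17 log2 in the NOD.LCMV response, 0.35 to 0.49 in the NOD.Ln82-LCMV response, 1.65 to 1.78 in their difference and 0.11 to 0.20 between the strains with the control peptide. Under other settings it ranged from 2.13 to 2.18, 0.28 to 0.44, 1.71 to 1.87 and 0.06 to 0.16, on the same side of the threshold throughout. Genes called in the NOD.LCMV response ranged from 3000 to 4271 without 1 array, in the difference between responses from 1207 to 1954, in the strain difference with gp33 from 4228 to 5641 and in the averaged strain difference from 4701 to 5956.

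A limit of 1.5-fold, by its construction, lowered the counts in limma to 0 in the NOD.Ln82-LCMV response (Cd69 rose 1.38-fold), 591 in the NOD.LCMV response, 456 in their difference, 110 in the strain difference with the control peptide, 703 with gp33 and 281 on average. Array weights raised the count to 4 in the NOD.Ln82-LCMV response, 3175 in the difference between responses and 4350 in the strain difference with the control peptide, and the variance trend gave 4 in the NOD.Ln82-LCMV response. For these the cause was not tested. Fitted on its own 9 arrays, the NOD.Ln82-LCMV response had 0 genes in limma (975 at an unadjusted p under 0.05). The block for shared replicate numbers also gave 0 (1300 unadjusted), as did the same 8 arrays without the block (0; 1391 unadjusted), so fewer samples account for that loss. Residuals of arrays that share a number did not correlate across genes (r between −0.15 and 0.08, against up to 0.42 for arrays that do not), so the mice were not treated as pairs. Without 1 array the NOD.Ln82-LCMV response had 0 to 2 genes in limma, with 641 to 1563 at an unadjusted p under 0.05: 2 without control replicate 1, gp33 replicate 2 or NOD.LCMV gp33 replicate 2, and 0 without any other NOD.Ln82-LCMV array. The strain difference with the control peptide ranged from 1049 (without NOD.LCMV control replicate 3) to 2721 (without NOD.Ln82-LCMV control replicate 1). It also fell to 1188 without NOD.Ln82-LCMV control replicate 3 and 1310 without NOD.LCMV control replicate 2. The activation score of the NOD.Ln82-LCMV response ranged from 0.153 (exact permutation p = 0.0536, without control replicate 1) to 0.205.

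Lists called by camera fell, with an estimated correlation, from 12 to 1 in the NOD.Ln82-LCMV response, 13 to 7 in the NOD.LCMV response, 12 to 7 in their difference, 14 to 6 between the strains with gp33 and 13 to 3 on average. With the control peptide they fell from 8 to 0 (1 at an unadjusted p under 0.05). Fry called 1 list there and 2 in the NOD.Ln82-LCMV response. It called 15 in the NOD.LCMV response, 11 in the difference between responses, 17 between the strains with gp33 and 11 on average. Without 1 array, 5 to 9 lists were called between the strains with the control peptide, 5 of them without NOD.Ln82-LCMV control replicate 2; the cause was not tested. The lower share of called genes on chromosome 7, 23.4% against 28.2% elsewhere, became a difference of −3.87 points (Fisher's exact test, adjusted p = 0.246) without the dimmest 33.3% of genes, whose removal leaves fewer genes, and −0.53 points (adjusted p = 0.682) for calls with the control peptide alone. It stayed past the threshold at an adjusted p under 0.01 (adjusted p = 0.0164) and for calls with gp33 alone (3.49e-07). Of 3249 values of named genes under other settings, 68 lost their call, as did 324 of 6480 with 1 array left out. Signal over background was not used here, and its effect on the dimmest genes was tested only by leaving them out.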

Other observations

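The tests in this part were chosen after the results were seen. MicroRNA genes, which the rule for named genes leaves out, were mostly higher in NOD.LCMV among those called. Of 300 microRNA genes on the array, 24 were called higher in NOD.LCMV with the control peptide, 63 higher and 3 lower with gp33, and 21 higher and 1 lower in the NOD.LCMV response to gp33. Mir142, a microRNA gene of blood cells, was chosen for naming after its values were seen. It stood between 8.53 and 9.45 log2 in the 3 NOD.LCMV mice given gp33, 7.55 and 8.29 in the 3 given the control peptide, and 6.14 and 7.14 in 8 of the 9 NOD.Ln82-LCMV mice, with 8.20 in control replicate 1.

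A hypothesis from these data is that the NOD.Ln82-LCMV response may be a smaller version of the NOD.LCMV response. Of 1453 genes that rose in NOD.LCMV, 76.8% had the same sign in NOD.Ln82-LCMV, and of 2490 that fell, 75.6%, against 57.2% of all genes. Across genes, which are not independent replicates, the responses correlated with r = 0.444 (0.366 without NOD.Ln82-LCMV control replicate 1). Over the 205 genes called at 2-fold or more in NOD.LCMV, the slope of the NOD.Ln82-LCMV response on the NOD.LCMV response was 0.131. This was larger than in any other of the 126 splits of the NOD.Ln82-LCMV arrays (exact permutation p = 0.00794, the smallest possible; largest other slope 0.123). Without control replicate 1 the slope was 0.0969 (exact permutation p = 0.0357 over 56 splits, 1 of which gave a larger slope of 0.0971). The test bears on direction only and leaves open why the response was smaller.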
